A study of Drosophila melanogaster with 4 samples.

How the data were processed

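Wing imaginal discs were taken from third-instar larvae raised at 25 °C. Per the labels' protocols, 80 to 100 discs of each genotype were pooled, total RNA was depleted of ribosomal RNA, and 4 µg went into a TruSeq RNA version 2 library, a kit that does not mark strand, sequenced on an Illumina HiScan. The deposited values are FPKM, fragments per kilobase of transcript scaled to library size, for 13990 genes in 4 libraries. Per the submitters' processing notes, the authors used CASAVA 1.4, TopHat2 2.0.12, Cuffdiff 2.2.1 and the dm6 genome build. The gene annotation and the options of these tools are not given in the sources used here. FPKM divides by transcript length and library size, so a group of genes that takes more of a library lowers the rest. Values of overlapping genes, antisense partners and near-identical family members (Hsp70, glutathione S-transferase, cuticle, histone and Gr64 genes) depend on how Cuffdiff shared fragments among them. An exact 0 can be a failed estimate, since 97 genes were listed at 0 in 1 library and at 10 FPKM or more in another. Such genes are described as listed at 0, with no fold.

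The depth behind the values was estimated from their steps. For single-transcript protein-coding genes with low FPKM, the depth was sought at which values become whole numbers of fragments after 210 nt is subtracted from the transcript length. At the best depth 74.1% to 77.9% of the values lay within 0.08 of a whole number, against 16.0% by chance, over 940 to 952 genes per library. The depths were 8.07 M fragments (GFP), 9.52 M (Yki), 12.4 M (Yki+Tai) and 8.27 M (Yki+Tai-IR). On a transcript of 2 kb, 3 fragments correspond to 0.208, 0.176, 0.135 and 0.203 FPKM in these libraries, and lower values are not resolved. Ratios carry an exact Clopper-Pearson interval at 95% on the estimated fragments. The intervals cover counting error only, not variation between pools. File symbols were matched to the Ensembl release 115 annotation of BDGP6, which has dm6 coordinates: 13857 matched, 3328 of them through an older symbol, and 133 did not.

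Before the data were examined, 4 comparisons were fixed: Yki against GFP, Yki+Tai against Yki, Yki+Tai-IR against Yki, and Yki+Tai against Yki+Tai-IR. With 1 library per genotype no test or p-value is possible. Genes were counted when their log2(FPKM + 1) differed by 1 or more, among 7777 genes with a mean of 1 FPKM or more over the 4 libraries. This scale understates the change of low genes. A set of 341 small-RNA genes was left out, but the 7SK small nuclear RNA has a name that escaped this filter and stays in the counts. Also fixed were 43 gene lists and families, of which 40 had the 3 measured members (mean of 0.1 FPKM or more) needed for a percentile. They cover Yki targets, the Hippo, ecdysone, JNK, JAK-STAT, Wnt, Notch, EGFR, Dpp and insulin pathways, germline, piRNA and spermatocyte genes, apoptosis, cell cycle, ribosome, respiration, polarity and stress genes, regions of the wing disc, roX RNAs, and markers of myoblasts, trachea, hemocytes, fat body, salivary gland, muscle, neurons, glia and gut. The list of mitochondrially encoded genes matched 0 genes. Each list median was placed among 10000 random lists of the same size, matched on mean expression in 10 bins. The percentile describes these libraries only. Over all lists and comparisons, 69 of 160 medians lay outside the central 95% of their random lists. Lists share members, so they are not independent. Overlap was counted only between comparisons with no library in common, beside the number expected of independent lists.

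Named genes followed a fixed rule. It took the 10 highest and 10 lowest differences of each comparison, a fixed set of transgene, compartment, Yki-target, germline and ecdysone genes, and the 2 to 4 members of each list with the largest difference. The 14 leg genes, the overlapping gene CG11779 and the local blocks of neighbouring genes were chosen after their values were seen. The counting and list steps were tested on simulated libraries with the depths of Yki and GFP. The simulation held counting noise only, so its rates leave out differences between pools and genes that vary together. Over 7732 simulated genes, 98.0% of those raised 4-fold and 92.0% of those lowered 2.5-fold passed the 2-fold limit, against 0.21% of unchanged genes. Of 100 lists of 25 unchanged genes, 2 lay outside their random range. The alternatives were a pseudocount of 0.1 or 5, no FPKM filter or one of 5, rescaling by the median ratio or to the same FPKM sum, and keeping small-RNA genes. Further alternatives left out genes listed at 0, genes under 500 nt, genes under 50 estimated fragments, or genes of other cell types and stress, and were chosen after seeing the data. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.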

Results

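RNA was sequenced from wing imaginal discs of third-instar Drosophila larvae, the epithelial sacs that form the adult wing and notum. Transgenes were driven with engrailed-GAL4, which is active in the posterior compartment of the disc, so each library mixes posterior cells that carry the transgene with anterior cells that do not. There were 4 genotypes and 1 pooled library of each: GFP alone, the Hippo-pathway coactivator Yorkie (Yki), Yki with the ecdysone receptor coactivator Taiman (Tai), and Yki with an inverted-repeat construct against tai (Yki+Tai-IR). The depth read from the steps between low FPKM values was 8.07 M fragments for GFP, 9.52 M for Yki, 12.4 M for Yki+Tai and 8.27 M for Yki+Tai-IR. With no replicate of any genotype, no difference below has a replicate check. Values describe these libraries, and intervals on ratios are 95% exact binomial intervals that cover counting error only. Sets of 4 FPKM values are given in the order GFP, Yki, Yki+Tai, Yki+Tai-IR.

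The targeted genes were examined first. Transcript of yki stood at 71.5 FPKM in GFP, 5034 in Yki, 4535 in Yki+Tai and 2563 in Yki+Tai-IR. The Yki+Tai-IR library thus held 0.509 times the yki signal of the Yki library (interval 0.502 to 0.516). Transcript of tai stood at 27.1, 25.0, 1260.3 and 22.9 FPKM. Its ratio of Yki+Tai-IR to Yki was 0.916 (0.865 to 0.97), so in whole discs the construct against tai was accompanied by a small difference in tai transcript. The posterior genes en, inv and hh were higher in Yki+Tai than in Yki, at 1.94 times (1.78 to 2.10), 2.2 times (2.08 to 2.33) and 1.33 times (1.22 to 1.46). The anterior gene ci went the other way, at 128, 81.3, 29.8 and 103 FPKM.

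**Figure D1:**
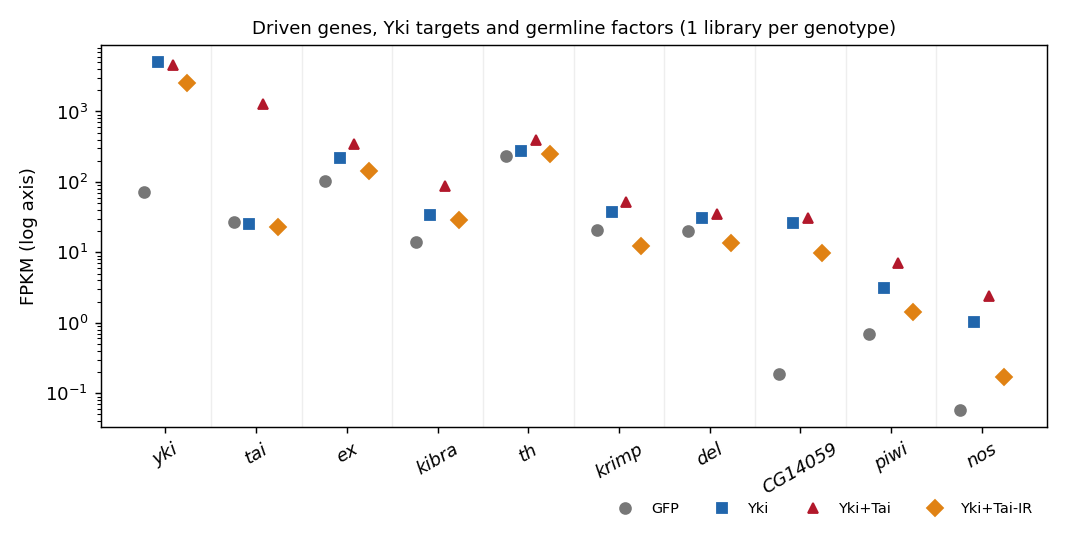
FPKM on a log axis (y) of 10 genes (x) in the 4 libraries, 1 point per library with no error bars because each genotype has 1 library. The points for ex, kibra, krimp, CG14059 (Ilp8), piwi and nos are highest in Yki+Tai, where nos reached 2.38 FPKM against 0.0578 in GFP.

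Comparing Yki with GFP asks what Yorkie alone does to the disc. Several known Yki targets were higher. The upstream Hippo-pathway genes ex and kibra stood at 222 and 33.8 FPKM in Yki against 104 and 14.1 in GFP, ratios of 2.13 (2.06 to 2.2) and 2.40 (2.19 to 2.63). The inhibitor of apoptosis th (Diap1) differed less, at 277 against 233 FPKM, a ratio of 1.19 (1.14 to 1.24). The targets fj, Mer, CycE, wg and dm (Myc) all differed by under 0.40 on the log2 scale. CG14059, which encodes the relaxin-like peptide Ilp8 that delays pupariation when discs grow abnormally, was at 26 FPKM against 0.188. The transcription factor gene chinmo was at 8.21 against 1.25 FPKM, and mol, a dual oxidase maturation factor gene, at 10.3 against 2.04. Of the 16 measured Yki targets, 2 were at least 2-fold higher and 0 lower. The median of the list was 0.14 on the log2(FPKM + 1) scale, at percentile 96.7 of random lists matched on expression. The Hippo-pathway list had a median of -0.096 over 41 genes, at percentile 4.58, with 3 genes 2-fold higher, of which yki is the transgene.

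Genes lower in Yki than in GFP included Notch-responsive, proneural, myoblast and muscle genes. In the Notch-pathway list 10 of 24 genes were at least 2-fold lower and 0 higher, with a median of -0.67 at percentile 0.0. Its members HLHmgamma, m2 and HLHm7, genes of the Enhancer of split complex, stood at 4.80, 37.2 and 23.3 FPKM against 15.9, 108 and 62.4. The notum list had a median of -0.58 over 14 genes, at percentile 0.0, and the proneural genes ac and sc were at 15.1 and 18 against 33.3 and 41.8 FPKM. Markers of the adepithelial myoblasts that lie under the disc had a median of -0.63, with 5 of 16 at least 2-fold lower, and twi was at 6.73 against 22.0 FPKM. Muscle genes had a median of -0.46, with 6 of 27 lower. The Hedgehog target ptc was at 21.5 against 54.0 FPKM. Among the 10 largest decreases were genes of the leg disc, a separate tissue that sits beside the wing disc. Sp1 stood at 0.144 against 43.9 FPKM, AP-2 at 0.570 against 37.6, and fd96Cb was listed at 0 against 46.2. The 7SK small nuclear RNA also stood among them, at 501 against 7134 FPKM, and was listed at 0 in both Yki+Tai and Yki+Tai-IR.

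Over 7777 genes with a mean of 1 FPKM or more, 144 were at least 2-fold higher in Yki than in GFP and 237 lower. Without the leg, myoblast, muscle, hemocyte, heat shock and fat body genes, an alternative chosen after seeing the data, the counts were 141 and 204. Heat shock genes were lower as a list, with a median of -0.63 over 19 genes at percentile 0.0 and 5 at least 2-fold lower. Hsp70Bbb went the other way, at 264 against 51.2 FPKM. DNA replication genes had a median of 0.11 over 41 genes, at percentile 98.7, and the oxidative phosphorylation list a median of -0.21 over 36 genes, at percentile 0.040. The counts move with the pseudocount: 233 genes were higher with 0.1 added in place of 1, and 57 higher and 95 lower with 5 added.

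**Figure D2:**
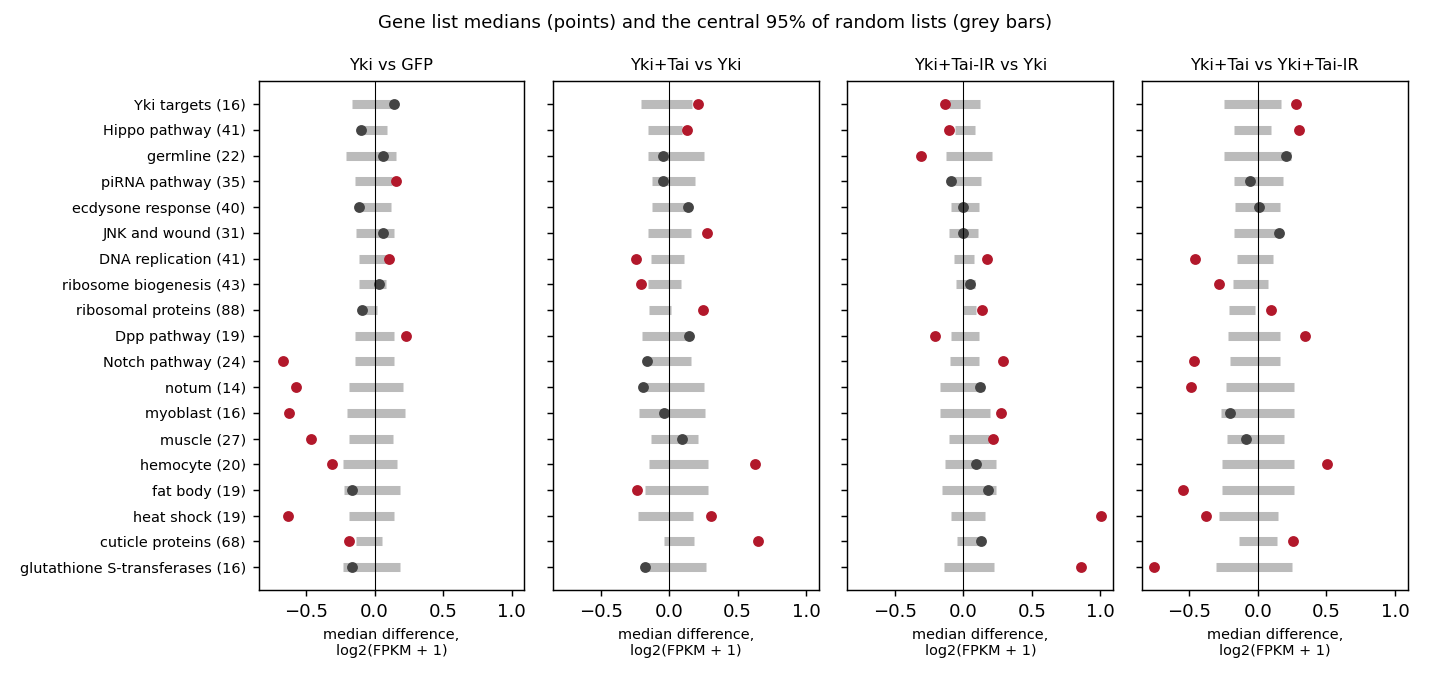
Median difference in log2(FPKM + 1) (x) of 19 gene lists (y, number of measured genes in brackets) in the 4 comparisons, 1 panel each, as points. Grey bars span the central 95% of 10000 random lists matched on expression, and red points lie outside them, such as the Notch-pathway list at -0.67 in Yki against GFP.

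Comparing Yki+Tai with Yki asks what added Taiman does in discs that already express Yki. The Yki targets ex, kibra and th were higher still, at 349, 87.4 and 389 FPKM against 222, 33.8 and 277. Their ratios were 1.57 (1.54 to 1.60), 2.58 (2.45 to 2.73) and 1.41 (1.36 to 1.45), and yki itself was at 0.901 times (0.891 to 0.911). The ratios of ex and th lie below those of the posterior genes en and inv, 1.94 and 2.2. They lie above that of the posterior gene hh, 1.33 (1.22 to 1.46), whose interval overlaps that of th. A larger posterior share is therefore not separated from an effect of Tai on ex and th. The ratio of kibra exceeds those of en, inv and hh. The list of 16 Yki targets had a median of 0.21, at percentile 99.2, with 1 gene at least 2-fold higher. Of the 16 targets 5 were below 0, among them wg at 25.7 against 40.3 FPKM, fj at 69.2 against 84.7 and CycE at 27.8 against 30.4. The Hippo-pathway list had a median of 0.13, at percentile 99.5, and wts, the kinase gene that restrains Yki, was at 43.7 against 24.3 FPKM. The JNK and wound list had a median of 0.28 over 31 genes, at percentile 99.9. In it scaf, a serine protease homologue gene, was at 83.7 against 28.6 FPKM and the translation repressor gene Thor at 44.5 against 17.7.

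Many cuticle genes were higher with added Tai. Of 68 measured cuticle protein genes, 29 were at least 2-fold higher and 5 lower, with a median of 0.65 at percentile 100.0. That median was 1.68 with a pseudocount of 0.1 and 1.32 among genes averaging 5 FPKM or more, but 0.0 with no FPKM filter, where members without signal enter. The cuticle list was lower in Yki than in GFP, with a median of -0.18 at percentile 0.36, 12 genes at least 2-fold lower and 6 higher, so part of the difference is measured from a low level in Yki. Cpr51A was at 413 against 94.7 FPKM, TwdlE at 135 against 21.8 and Cpr47Ee at 13.1 against 0.0886 (2.31 in GFP), while Cpr49Ah was lower, at 14.5 against 105. Osi6 and Osi7 were at 19.1 and 24.4 FPKM against 0.312 and 0.335. In the ecdysone-response list, 9 of 40 genes were at least 2-fold higher and 3 lower, with a median of 0.14 at percentile 95.1. Between Yki+Tai and Yki+Tai-IR this list did not stand apart, with a median of 0.005 at percentile 53.6, 7 genes at least 2-fold higher and 3 lower. The ecdysteroid hydroxylase gene Cyp18a1 was at 23.2 against 8.43 FPKM and ImpL3, lactate dehydrogenase, at 68.1 against 12.0. In Yki+Tai-IR, Cyp18a1 was at 5.22 FPKM, but ImpL3 was above Yki there too, at 48.2. The nuclear receptor gene Hr46 (Hr3) was lower, at 0.236 against 4.28. The receptor genes EcR and usp and the early genes Eip74EF, Eip75B and br differed by under 0.50 on the log2 scale.

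Genes for DNA replication and ribosome biogenesis had medians below 0 with added Tai, by less than 2-fold. Of 41 replication genes 39 were below 0 and 0 were 2-fold lower, with a median of -0.24 at percentile 0.030. RfC3 and RnrS stood at 22.7 and 103 FPKM against 36.9 and 162. The ribosome biogenesis list had a median of -0.21 over 43 genes, at percentile 0.14, with 37 below 0 and 0 at least 2-fold lower. Its member CG8801 was 2-fold higher, at 1028.9 against 480.3 FPKM, and cytosolic ribosomal protein genes had a median of 0.25 over 88 genes, at percentile 100.0. The ribosomal protein list was also higher in Yki+Tai-IR than in Yki, with a median of 0.134 at percentile 100.0 and 80 genes above 0. Between Yki+Tai and Yki+Tai-IR its median was 0.097, at percentile 100.0. Hemocyte markers were higher too. Of 20 measured markers of these blood cells, 5 were at least 2-fold higher and 0 lower, with a median of 0.63 at percentile 100.0, and nimC1 stood at 7.70 against 0.341 FPKM. The hemocyte list was lower in Yki than in GFP, with a median of -0.31 at percentile 0.42 and 16 genes below 0, so this difference too is measured from a low level in Yki. Heat shock genes were also higher, 8 of 19 by at least 2-fold, with Hsp68 at 178 against 7.17 FPKM (22.0 in GFP). Their median was 0.31, after one of -0.63 in Yki against GFP, so they too are measured from a low level in Yki. The leg gene Sp1 was at 12.4 against 0.144 FPKM. In all, 270 genes were at least 2-fold higher in Yki+Tai than in Yki and 164 lower. With 5 added in place of 1, the counts were 129 and 66.

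Comparing Yki+Tai-IR with Yki asks which of these features need endogenous tai. Its limits include the lower yki signal of the Yki+Tai-IR library and tai transcript at 0.916 times Yki. The leg disc genes also differed, with a median of 0.689 times GFP in Yki+Tai-IR against 0.007 in Yki. The Yki targets ex and kibra stood at 143 and 28.5 FPKM against 222 and 33.8, ratios of 0.644 (0.626 to 0.662) and 0.842 (0.783 to 0.904). Myc, listed as dm, was at 36.2 against 58.9 FPKM, and th at 251 against 277. The Yki target list had a median of -0.14, at percentile 0.83, with 0 genes past 2-fold in either direction. CG14059 (Ilp8) was at 9.66 against 26 FPKM, a ratio of 0.371 (0.267 to 0.509), whereas chinmo was at 8.18 against 8.21. The piRNA-pathway list did not stand apart, with a median of -0.092 at percentile 3.66, 3 genes at least 2-fold lower and 1 higher. Its members krimp and del were at 12.2 and 13.6 FPKM against 37.2 and 31.0, which is 0.595 (0.503 to 0.701) and 0.684 (0.595 to 0.787) times GFP, while spn-E was at 5.53 against 1.80. The wing pouch and Dpp-pathway lists had medians of -0.34 over 17 genes and -0.21 over 19, at percentiles 0.0 and 0.010. Both lists were higher in Yki than in GFP, with medians of 0.196 and 0.232 at percentiles 98.8 and 99.9. Part of this difference is therefore measured from a high level in Yki.

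Stress and detoxification genes were higher in Yki+Tai-IR. Heat shock genes had a median of 1.01 over 19 genes, at percentile 100.0, with 10 at least 2-fold higher. Hsp68, Hsp22 and Hsp26 stood at 335, 171 and 1064 FPKM against 7.17, 4.66 and 143, with 22.0, 12.6 and 421 in GFP. The heat shock list was lower in Yki than in GFP, so part of the difference is measured from a low level in Yki. The heat shock median was 1.67 with a pseudocount of 0.1. The glutathione S-transferase genes had a median of 0.86 over 16 genes, at percentile 100.0, with 6 at least 2-fold higher, and GstE6 was at 32.6 against 6.02 FPKM. The wider redox and detoxification list had a median of 0.29 over 31 genes, at percentile 100.0, with 8 at least 2-fold higher. Muscle genes had a median of 0.22 over 27 genes, with 9 at least 2-fold higher, but the median was -0.073 among members averaging 5 FPKM or more. The Notch-pathway list had a median of 0.29 over 24 genes, at percentile 100.0, after one of -0.67 in Yki against GFP. Myoblast markers had a median of 0.275 over 16 genes, at percentile 99.6, with 12 above 0. Leg genes were again higher here, with Sp1 at 27.9 against 0.144 FPKM. The odorant-binding protein gene Obp56d was at 443 against 0.554 FPKM. Altogether 249 genes were at least 2-fold higher and 72 lower. With 0.1 added in place of 1, 149 genes were lower.

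Comparing Yki+Tai with Yki+Tai-IR sets added Tai against the construct against tai, in discs with Yki, and bears on the germline stem cell factors named in the title of the series. The translational repressor gene nos (nanos, FBgn0002962, chromosome 3R, 19157238 to 19160202 in dm6) stood at 0.0578, 1.02, 2.38 and 0.168 FPKM, about 1, 21, 63 and 3 fragments. Its ratio of Yki+Tai to Yki+Tai-IR was 14.2 (4.64 to 70.7). The annotated span of nos overlaps that of CG11779 on the other strand, and the library kit does not mark strand. CG11779 itself was flat, at 19.5, 21.0, 20.6 and 19.9 FPKM. The PIWI-family gene piwi (FBgn0004872, chromosome 2L, 10982205 to 10987420) stood at 0.690, 3.16, 7.06 and 1.42 FPKM, a ratio of 4.97 (3.46 to 7.34) between Yki+Tai and Yki+Tai-IR. Over Yki, the ratios of Yki+Tai were smaller, 2.33 (1.4 to 4.02) for nos and 2.23 (1.74 to 2.88) for piwi. The ratio of Yki to GFP for piwi was 4.59 (2.67 to 8.38). The differentiation factor gene bam was listed at 0 in GFP and stood at 1.57, 2.13 and 0.936 FPKM in the others, a ratio of 2.28 (1.21 to 4.60) between Yki+Tai and Yki+Tai-IR. The germline helicase gene vas was also highest in Yki+Tai, at 0.357, 0.201, 0.920 and 0.346 FPKM, a ratio of 2.66 (1.06 to 7.96) that rests on about 24 and 6 fragments.

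As a list, germline genes did not stand apart in this comparison. Of 22 measured genes 2 were at least 2-fold higher and 1 lower, with a median of 0.20 at percentile 95.2. Against Yki, the list was lower in Yki+Tai-IR, with a median of -0.31 at percentile 0.0, and not apart in Yki+Tai, with a median of -0.043 at percentile 18.4. It was not apart in Yki against GFP either, with a median of 0.064 at percentile 86.1. The piRNA-pathway list had a median of -0.061 over 35 genes, at percentile 23.3. It was higher in Yki than in GFP, with a median of 0.16 at percentile 99.1 and 25 genes above 0, and not apart in Yki+Tai against Yki, with a median of -0.042 at percentile 19.5. It included krimp at 51.2 FPKM in Yki+Tai against 12.2 in Yki+Tai-IR, a ratio of 4.2 (3.66 to 4.84), but spn-E at 1.96 against 5.53.

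Yki targets were higher as a list, though not throughout, in Yki+Tai than in Yki+Tai-IR. The list had a median of 0.28, at percentile 99.8, with 10 of 16 genes above 0, 6 below and 2 at least 2-fold higher. Ratios were 2.44 for ex (2.38 to 2.5), 3.07 for kibra (2.89 to 3.26) and 1.55 for th (1.49 to 1.60). Among the targets below 0, wg was at 0.602 (0.549 to 0.661), CycE at 0.87 and fj at 0.917. The Hippo-pathway list had a median of 0.30, at percentile 100.0, with 5 of 41 genes at least 2-fold higher, of which tai is the transgene. Replication genes had a median of -0.46, with 41 of 41 below 0. Part of this lies in Yki+Tai-IR, where the list had a median of 0.17 against Yki, with 32 of 41 above 0. Cuticle genes were higher, with 20 of 68 at least 2-fold higher, 9 lower and a median of 0.26. Glutathione S-transferase genes had a median of -0.76, with 7 of 16 at least 2-fold lower, and the Notch-pathway list a median of -0.47, with 6 of 24 lower. The notum list had a median of -0.49 at percentile 0.020. The myoblast and muscle lists did not stand apart, with medians of -0.20 at percentile 6.24 and -0.089 at percentile 23.4, though 4 of 16 and 9 of 27 genes were at least 2-fold lower. The median leg gene stood at 0.226 times GFP in Yki+Tai against 0.689 in Yki+Tai-IR. The posterior genes en, inv and hh were at 2.65 times (2.40 to 2.92), 2.29 times (2.15 to 2.43) and 1.46 times (1.33 to 1.61), and yki at 1.77 times (1.75 to 1.79). The ratios of ex and th did not exceed that of en here either. That of ex did exceed hh, and that of kibra lay above en with overlapping intervals. Hemocyte markers had a median of 0.50, with 6 of 20 at least 2-fold higher. In all, 289 genes were at least 2-fold higher and 342 lower.

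The overlap of Yki against GFP with Yki+Tai against Yki+Tai-IR asks whether genes that differ with Yki also differ between Yki+Tai and Yki+Tai-IR. These comparisons share no library, but yki itself was 1.77 times higher in Yki+Tai than in Yki+Tai-IR, so overlap in the same direction can follow from the yki level as well as from Tai. Of the 144 genes higher with Yki, 31 were also higher in Yki+Tai, against 5.4 for independent lists of the same sizes, and they include ex, kibra, piwi and CG14059. Of the 237 genes lower with Yki, 84 were also lower in Yki+Tai, against 10.4, and they include twi, ac, sc and Sp1. The crossed overlaps were smaller but also above independence, 23 against 6.3 for higher then lower and 30 against 8.8 for lower then higher. Across the 7777 genes the correlation of the differences was 0.035, and genes are not independent replicates. Without the leg, myoblast, muscle, hemocyte, heat shock and fat body genes, the overlaps in the same direction were 30 and 60.

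**Figure D3:**
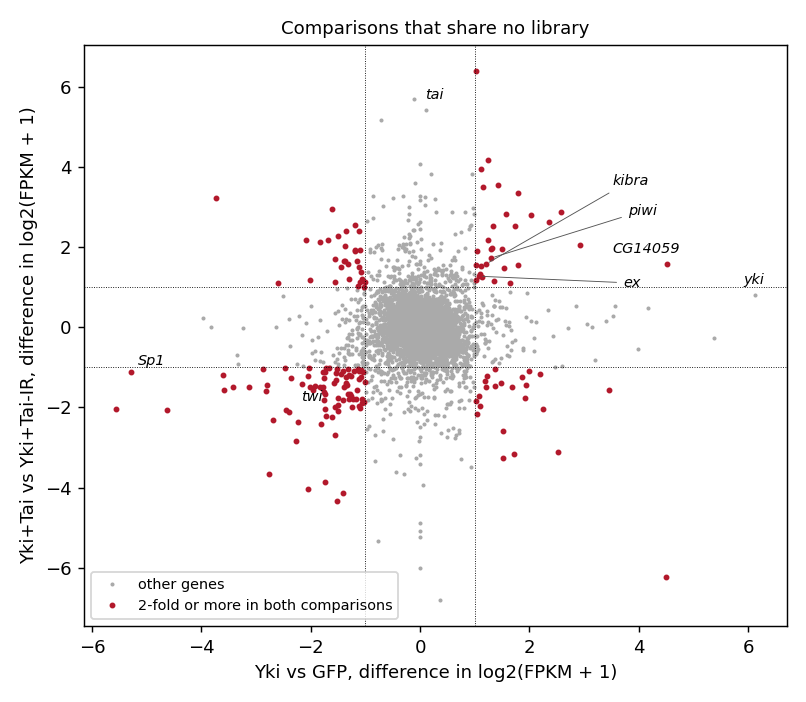
Each point is 1 of 7777 genes, placed by its difference in log2(FPKM + 1) in Yki against GFP (x) and in Yki+Tai against Yki+Tai-IR (y), with dotted lines at 2-fold. Red points passed 2-fold in both comparisons, 84 of them in the lower left corner and 31 in the upper right.

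**Figure D4:**
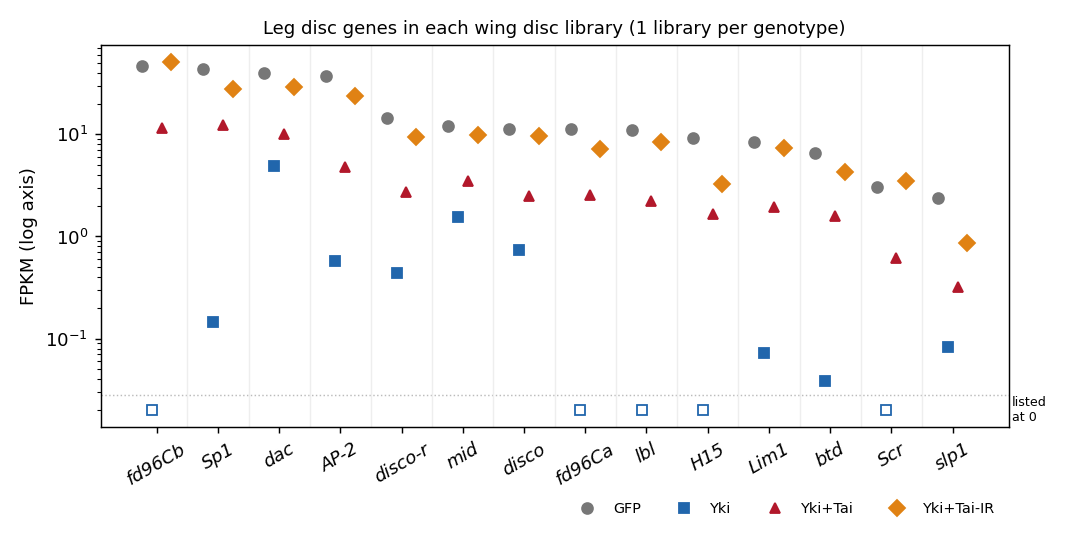
FPKM on a log axis (y) of 14 leg disc genes (x) in the 4 libraries, 1 point per library; open squares on the bottom line are genes listed at 0. The Yki points lie lowest for each of the 14 genes, and the Yki+Tai points lie between 0.128 and 0.288 times GFP.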

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

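The last 3 alternatives in this paragraph and the one that leaves out genes listed at 0 were chosen after seeing the data. No paired analysis was possible because each genotype has 1 library and no replicate numbers. Counts of genes past 2-fold moved by over 1.5 times in 20 cases, none of them under rescaling, and stayed within it in 68. List medians shifted by log2 of 1.5 or more in 13 cases and by less in 1094. That limit is larger than most of the medians, so a shift within it says little about robustness. Of the medians outside their random range 1 changed sign, and sign changes of the others were not counted. Rescaling factors lay between 0.973 and 1.02. The Yki target medians lay between 0.11 and 0.20 for Yki against GFP, 0.13 and 0.22 for Yki+Tai against Yki, -0.21 and -0.12 for Yki+Tai-IR against Yki, and 0.23 and 0.32 for Yki+Tai against Yki+Tai-IR. With a pseudocount of 0.1, 233 genes were higher in Yki than GFP, 247 lower in Yki+Tai than Yki and 149 lower in Yki+Tai-IR than Yki, and the overlaps were 59 higher in both, 135 lower in both, 50 higher then lower and 48 lower then higher. With a pseudocount of 5, the counts of higher and lower genes were 57 and 95 for Yki against GFP, 129 and 66 for Yki+Tai against Yki, 89 and 28 for Yki+Tai-IR against Yki, and 154 and 146 for Yki+Tai against Yki+Tai-IR, and the overlaps in the same order were 12, 18, 6 and 6. A larger pseudocount shrinks the differences of low genes by construction. Among genes with a mean of 5 FPKM or more, fewer genes enter: 91 were higher and 128 lower in Yki than GFP, 135 higher in Yki+Tai than Yki, 99 higher and 38 lower in Yki+Tai-IR than Yki, and 173 higher and 196 lower in Yki+Tai than Yki+Tai-IR, with overlaps of 49 lower in both, 10 higher then lower and 15 lower then higher. There the muscle median for Yki+Tai-IR against Yki changed sign, to -0.073, as low muscle genes left the list. With small-RNA genes kept, 115 genes were lower in Yki+Tai-IR than Yki and 51 lower then higher. Without genes under 500 nt, 14 were higher then lower. Without genes under 50 estimated fragments, 162 were higher in Yki+Tai-IR than Yki and 11 higher then lower. Without genes of other cell types and stress, no count or overlap moved by over 1.5 times. The value of nos rests on about 1 fragment in GFP and 3 in Yki+Tai-IR.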

Other observations

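The tests in this part of leg genes, neighbouring genes, nos and piwi were chosen only after the results were seen; the gene lists were fixed before. Further tissue and pathway groups differed between libraries. In the hinge list the median for Yki+Tai against Yki was -0.40 over 8 genes, at percentile 0.22, and drm was at 21.7 against 44.6 FPKM. The EGFR list had a median of -0.14 over 21 genes in Yki against GFP, at percentile 2.5, with rho at 3.19 against 9.72 FPKM. Mitosis genes had a median of 0.082 over 40 genes in Yki+Tai-IR against Yki, at percentile 97.8, and the Wnt list a median of -0.11 over 26 genes, at percentile 1.11. In the same comparison the cell polarity and adhesion list had a median of -0.13 over 24 genes, at percentile 0.020, and the insulin and TOR list a median of -0.11 over 25 genes, at percentile 2.47. The anterior list had a median of -0.48 over 4 genes in Yki against GFP, at percentile 0.44, and the posterior list one of 0.93 over 3 genes in Yki+Tai against Yki, at percentile 100.0. The roX RNAs of X-chromosome dosage compensation, made in males, stood at 136, 324, 222 and 202 FPKM for roX1 and 103, 270.3, 165 and 144 for roX2. Both were at least 2-fold higher in Yki than in GFP, and a different share of males in the pools was not tested. The Hox gene Ubx stood at 66.0, 121, 77.7 and 96.7 FPKM.

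Other cell types gave a mixed picture. Fat body genes had a median of -0.55 over 19 genes in Yki+Tai against Yki+Tai-IR, at percentile 0.010, with Pepck at 39.0 against 179 FPKM. Tracheal genes had a median of 0.25 over 12 genes in the same comparison, at percentile 98.9. Salivary gland genes had a median of 1.02 over 9 genes in Yki against GFP, with Sgs7 at 4.77 FPKM and listed at 0 in GFP. The higher glue genes rest on few fragments, 5 for Sgs7 and 7 for Sgs5 in Yki, and Sgs3 was listed at 0 in Yki and at 0.275 FPKM in GFP. The chorion and vitelline family, matched by gene name, had a median of -0.36 over 6 genes in Yki against GFP, at percentile 1.68. The name match also took in Cp1 (CtsL1) and Cp110, which are not eggshell genes. Its members Cp15, Cp18 and Vm34Ca rest on at most 5 fragments in GFP and at most 1 in Yki, so the median says little about eggshell genes. In Yki+Tai against Yki+Tai-IR several lists lay inside their random range. Medians there were 0.085 for apoptosis (20 genes), -0.036 for JAK-STAT (14), -0.20 for spermatocytes (7), 0.14 for neurons (9), -0.28 for glia (10), 0.052 for histones (6) and 0.0 for antimicrobial genes (21). Of the gut list 2 genes were measured, and Jon65Aiv did not exceed 0.512 FPKM.

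All 14 leg disc genes were lower in Yki than in GFP, with 5 listed at 0, and the medians were 0.00700 times GFP in Yki, 0.226 in Yki+Tai and 0.689 in Yki+Tai-IR. Different amounts of leg disc tissue in the pools may account for this. The log2 ratios of Yki+Tai to GFP had an SD of 0.311 over the genes, against a median of 1.29 for random lists. Those of Yki+Tai-IR had an SD of 0.473, against 1.09. The leg genes were chosen after their values were seen, so a smaller SD than in random lists is partly built in and cannot decide this. An effect of Yki of similar size in every library with the transgene is argued against by the median of 0.689 in Yki+Tai-IR. An effect in proportion to the yki level would leave Yki+Tai close to Yki, since it held 0.901 times the yki signal of Yki (0.891 to 0.911). The median leg gene stood at 0.226 times GFP there against 0.00700 in Yki, which argues against proportion for the set. The leg genes lay between 0.128 and 0.288 times GFP in Yki+Tai, and at most at 0.127 in Yki. Single genes were not set against the value that proportion predicts for them, and each genotype has 1 library. A steeper graded effect stays open, since the medians are lower where yki is higher. Yki+Tai-IR held 0.509 times the yki signal of Yki. Anterior cells carry no transgene, so an effect confined to posterior cells would leave any anterior leg gene signal in place. With all 14 genes at most at 0.127 times GFP in Yki, such an effect needs little anterior signal or a reach beyond posterior cells. An effect that also needs endogenous tai stays open too. Myoblast, Notch and proneural genes, some of which the leg disc also uses, were lower in Yki than in GFP as the leg genes were. In Yki+Tai, ac, sc and twi did not follow the leg genes, at 5.65, 6.03 and 3.81 FPKM against 15.1, 18 and 6.73 in Yki. In Yki+Tai-IR they stood above Yki as the leg genes did, at 25.6, 23.3 and 11.7 FPKM. The Notch-pathway list was higher than in Yki there too, with a median of 0.29. A part of leg tissue in these differences thus stays open.

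Of 26 genes at 0.1 FPKM or less in GFP and at least 2-fold higher in Yki, 8 lay next to another, against at most 4 in 10000 random gene sets. Neighbouring genes that move together fit an insertion or a haplotype of the stocks, but the 8 genes come from 2 loci, so the other genes are not covered. The smaller locus holds the salivary glue genes Sgs7 and Sgs8, at about 5 fragments each in Yki, for which salivary gland tissue in the pool was not tested. In the larger locus, on chromosome 3L, the 6 Gr64 taste receptor genes were at most 0.0927 FPKM in GFP and Gr64a stood at 16.9, 18.1 and 12.6 FPKM in Yki, Yki+Tai and Yki+Tai-IR. With their neighbour CG11594, at 0.853 FPKM in GFP and 12.3 in Yki, they span 4022700 to 4037575 in dm6. Gr64b and Gr64c have the same annotated span and Gr64d and Gr64e overlap, so part of the adjacency follows from the annotation. Shared transcripts or an effect of Yki at this locus stay open. On chromosome 3R from 17415739 to 17422202, 4 neighbouring genes were high in Yki+Tai-IR, with CG33333 at 258 FPKM, while Hsc70-2 stood at 14.2, 14.1, 0.0405 and 0.0608 FPKM.

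For nos and piwi, highest in Yki+Tai, gonad tissue in the pools stays open: vas, aub, bgcn, Rbp9, zpg and osk together held 54 fragments in Yki+Tai against 49 in Yki+Tai-IR, 0.735 times after depth scaling (0.490 to 1.10), with a median ratio of 0.685 for the 4 that have a ratio. However, Rbp9, zpg and osk lie under the resolved level in Yki+Tai, and vas at 2.66 (1.06 to 7.96) and bam at 2.28 (1.21 to 4.60) go with nos. A larger posterior compartment as the whole cause of the ratios between Yki+Tai and Yki+Tai-IR is argued against by the highest posterior ratio, 2.65 for en, below the lower limits of 4.64 for nos and 3.46 for piwi. Posterior share stays open for Yki+Tai over Yki, where nos at 2.33 (1.4 to 4.02) and piwi at 2.23 (1.74 to 2.88) lie close to inv at 2.2, and as a part of the cause beside the yki level. In Yki+Tai-IR, the lower yki signal cannot be told apart from an effect of the construct against tai, whose target transcript was at 0.916 times Yki: interpolated by yki level, nos would stand at 0.542 FPKM or 9.7 fragments (4 to 16) where 3 were seen, and piwi at 46.2 fragments (33 to 60) where 34 were seen, so the hypothesis that the Tai level itself sets both genes stays open.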
